A study of Homo sapiens with 32 samples.

How the data were processed

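Macrophages derived from blood mononuclear cells of 8 human donors received DMSO, IFN-γ, LCL161 (500 nM) or LCL161 with IFN-γ for 24 h, which gave 32 libraries, 8 per group. The series' design text states that the cells of each donor received every treatment; lymphotoxin arms that it also mentions have no libraries here and were not analysed here. The deposited table holds expected counts (estimated counts) per gene, which the authors did not normalise; 51.8% of its values above 0 are not whole numbers. Per the submitters' processing notes, reads were trimmed with cutadapt and aligned to hg38 with STAR 2.7.3a. The counting tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with close copies or with a neighbour that shares their exonic bases therefore carry an uncertain share of each other's reads; 46 of the 119 named genes share exonic bases with another gene, 19 on the same strand and 36 on the opposite strand.

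The table has 62757 rows, of which 62686 carry a symbol. Because the cells are from human donors, 573 rows of Y-linked genes, their pseudoautosomal copies, XIST and TSIX were removed before any test, and 62184 were kept, 41667 of them with a count above 0. Expected counts were rounded to whole numbers, which changed a library's total by at most 0.0031%. Library totals ran from 18.7 to 28.2 M, which is the precision behind each CPM; counts are reads without molecular identifiers. Coordinates are 1-based and from GENCODE on GRCh38, matched by gene identifier.

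The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr on group (17841 genes kept), TMM factors (0.9 to 1.16), robust dispersion and robust quasi-likelihood F tests, with the donor as a block plus group, on all 32 libraries in 1 fit. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The standard error is the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 15.2% and the median prior degrees of freedom 5.5. The comparisons were each treatment against DMSO, the combination against each single treatment, LCL161 against IFN-γ, and the interaction, which is the LCL161 effect with IFN-γ minus the effect without it. The pairing was checked on 2000 genes after group means were removed: the correlation over the 48 pairs of libraries of the same donor was at least 0.61 (median 0.83), against a median of -0.14 over pairs of different donors.

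For 42 gene lists, limma 3.58.1 camera compared each list with all other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Each list was also tested with an estimated correlation and with fry, a rotation test of whether its genes move one way on balance. Shares of counts were compared with exact paired permutation tests (sign flips within donors, 2-sided, smallest possible p 0.0078), adjusted over 52 tests. Overlaps of calls are given beside the product of both counts divided by 17841. Simulated unchanged groups (for correlations) and disjoint sets of 4 donors served as background where the comparisons share DMSO libraries. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.

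Named genes follow a rule: per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean log2 CPM of at least 3 and the same direction in all 8 donors; per list described, up to 4 called members with the smallest p; and 19 genes always named where measured. A selection of the genes that the rule gives is printed, and some genes are not reported here. GABBR1 and IER3-AS1 fall outside it and were chosen after their values were seen. The tests, lists, named-gene rule and alternatives were set before the data were examined. Alternatives were RLE and upper-quartile factors, no filter on low counts, at least 1 CPM in 8 libraries, DESeq2 1.42.0, limma-voom, non-robust edgeR, no replicate block, only the groups compared, a test against a fold of 1.5, and leaving out each donor in turn. A block by donor and IFN-γ state was added after the data had been seen. The procedure was also tested on simulated data with 17841 genes, 50 of them changed at each size. Of these, 28% were called at a fold of 1.25, 58% at 1.5, 88% at 2 and 100% at 4, with 6 false calls of 143. Of the simulated interactions of a fold of 4, 88% were called. The simulated groups held no effect of IFN-γ, so that share need not hold for genes that IFN-γ changed in these data.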

Results

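RNA was sequenced from macrophages grown from blood mononuclear cells of 8 human donors. The cells of each donor were split over 4 treatments of 24 h: the solvent DMSO, interferon gamma (IFN-γ), LCL161 at 500 nM, and LCL161 together with IFN-γ. LCL161 is a SMAC mimetic, a small molecule that binds inhibitor of apoptosis (IAP) proteins in the way the cellular protein SMAC does. IFN-γ is a cytokine that activates macrophages. The 32 libraries, 8 per group, held 18.7 to 28.2 M counts each, with a median of 23.9 M. Group means were 23.66 ± 2.48 M (SD, n = 8) for DMSO, 23.96 ± 2.59 M for IFN-γ, 24.67 ± 2.21 M for LCL161 and 23.13 ± 2.15 M for LCL161 with IFN-γ. Changes below are log2 fold changes ± the standard error from the edgeR fit of all 32 libraries with the donor as a block. This error pools the spread over all groups and is not the spread of the paired differences of the 8 donors. Changes were tested in 17841 genes with edgeR's quasi-likelihood test within donors and called at a Benjamini-Hochberg adjusted p below 0.05. Levels are means over the 8 libraries of a group in CPM, counts scaled to the library size.

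After the donor means were removed, IFN-γ and LCL161 separated the libraries along different axes. The first principal component held 52.8% of the variance and placed the libraries with IFN-γ at mean scores of 38.1 ± 13.7 (SD, n = 8) without and 39.3 ± 14.1 with LCL161, against -39.8 ± 14.1 for DMSO and -37.7 ± 13.7 for LCL161. The second component held 13.3% and placed the libraries with LCL161 at -17 ± 6.7 without and -21.5 ± 8.5 with IFN-γ, against 16.4 ± 5.9 for DMSO and 22.2 ± 6.5 for IFN-γ.

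**Figure D1:**
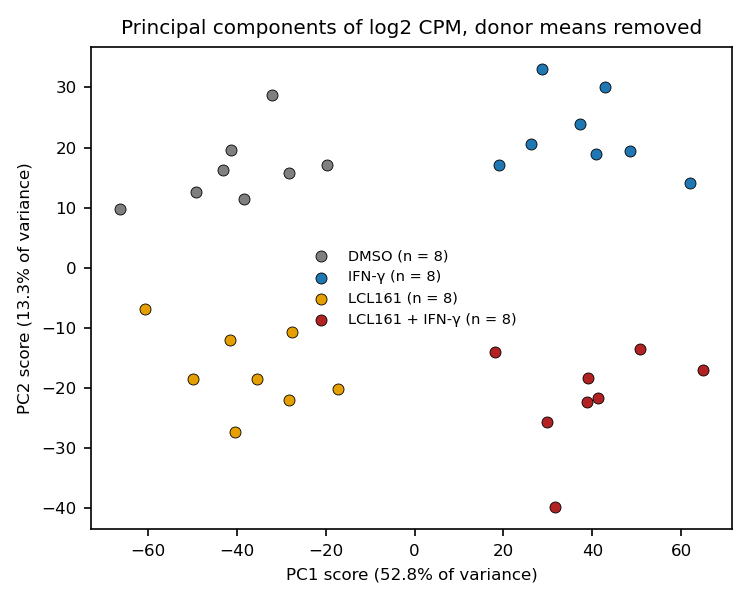
Principal component scores of log2 CPM with donor means removed, first component (52.8% of the variance) on the x axis and second (13.3%) on the y axis, 1 point per library and 8 per group. All libraries with IFN-γ lie right of 0 and all without it left of 0, and all libraries with LCL161 lie below 0 and all without it above.

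The comparison of LCL161 with DMSO asks which transcripts the SMAC mimetic alone changed in resting macrophages. LCL161 raised NF-kB pathway genes and genes of mature dendritic cells, and lowered part of the receptors for uptake, complement genes and lysosomal genes. The lysosomal list was not called with an estimated correlation (adjusted p = 0.277). With an estimated correlation and a block by donor and IFN-γ state, non-canonical NF-kB stayed called (adjusted p = 0.0298). The calls of the canonical NF-kB, mature dendritic cell and granulocyte lists (0.058 each) and of the IAP, phagocytic receptor and complement lists (0.0763 each) were then lost. MAP3K14, which encodes the NF-kB-inducing kinase NIK, rose by 1.83 ± 0.15, from 15.2 to 54.0 CPM (n = 8, edgeR adjusted p = 2.18e-08). BIRC3, which encodes cIAP2, rose by 2.11 ± 0.24, and TRAF1, an adaptor of TNF receptors, by 2.24 ± 0.28. The chemokine CCL17 rose by 4.22 ± 0.32, from 2.2 to 38.9 CPM. CD14, the lipopolysaccharide co-receptor, had a change of -1.06 ± 0.18, from 1617 to 837 CPM, lower in 8 of 8 donors. In GRCh38, MAP3K14 lies on chromosome 17, 45263119 to 45317145, BIRC3 on chromosome 11, 102317450 to 102339403, TRAF1 on chromosome 9, 120902393 to 120929173, CCL17 on chromosome 16, 57404767 to 57416062 and CD14 on chromosome 5, 140631728 to 140633701, all annotated as protein-coding genes.

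In the list of 17 measured non-canonical NF-kB genes, 8 rose and 1 fell over all genes, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 3.7e-09, and adjusted p = 0.0113 with an estimated correlation). Its members NFKB2, whose product is processed to p52, rose by 1.34 ± 0.16, and TRAF3, a negative regulator of NIK, by 0.51 ± 0.077. RELB, the partner of p52, rose by 0.53 ± 0.16 with an adjusted p of 0.0332. All 3 IAP genes were measured: BIRC3 and BIRC2 (cIAP1, 0.31 ± 0.082, adjusted p = 0.0159) rose, while XIAP had a log2 change of 0.20 ± 0.088 and was not called (adjusted p = 0.142). For this list, the counts were 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.17e-05, and adjusted p = 0.0368 with an estimated correlation). Of 28 canonical NF-kB feedback genes and targets, 12 rose and 0 fell (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.62e-16, and adjusted p = 0.0368 with an estimated correlation). They included NFKBIA, the inhibitor that NF-kB itself induces, at 1.12 ± 0.16, and CFLAR, an inhibitor of caspase-8, at 0.44 ± 0.078.

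Of 26 measured genes of mature dendritic cells 13 rose and 0 fell (15 higher and 0 lower adjusted over the list alone), with a median change of 0.57 (camera adjusted p = 1.41e-11, and adjusted p = 0.0368 with an estimated correlation). Members such as BIRC3, TRAF1 and CD83 are also in the canonical NF-kB list, and BIRC3, RELB, CCL19 and CD40 in the non-canonical one. CCR7, the receptor that guides cells to lymph nodes, rose by 2.15 ± 0.24, from 21.4 to 114 CPM. IL7R, the interleukin-7 receptor, rose by 1.36 ± 0.24. Outside this list, CYP27B1, which makes active vitamin D, rose by 1.92 ± 0.23 and TNFRSF9, the receptor 4-1BB, by 1.47 ± 0.23. Of 27 chemokines 5 rose and 1 fell (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0735), and of 34 TNF family ligands and receptors 4 rose and 4 fell (7 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.434). Among 16 inflammatory cytokines 1 rose and 0 fell (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.127). TNF had a log2 change of 0.01 ± 0.30 and IL1B of 0.76 ± 0.29, with adjusted p of 0.995 and 0.0922. IL1B was higher in 8 of 8 donors. It was called in the fit of these 2 groups alone (adjusted p = 0.000617), with a block by donor and IFN-γ state (0.00446) and with 1 donor left out (0.0471), with a highest adjusted p of 1 over the alternatives.

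Among uptake and degradation genes, more were called lower than higher with LCL161. Of 42 phagocytic and efferocytic receptors 0 rose and 17 fell (0 higher and 21 lower adjusted over the list alone; camera adjusted p = 9.48e-10, and adjusted p = 0.0368 with an estimated correlation). They included the scavenger receptor STAB1 at -0.87 ± 0.17, the complement receptor VSIG4 at -0.68 ± 0.15, and the Fc receptors FCGR2A at -0.64 ± 0.13 and FCGR1A at -0.70 ± 0.19 (adjusted p = 0.0177), which have close gene copies. MERTK, a receptor for apoptotic cells, had a log2 change of -0.34 ± 0.22, the mannose receptor MRC1 of -0.45 ± 0.21 and the haemoglobin receptor CD163 of -0.50 ± 0.22, and none of these 3 was called (adjusted p = 0.338, 0.194 and 0.15). MRC1 was lower in 8 of 8 donors. It was called in the fit of these 2 groups alone (adjusted p = 0.00375) and with the block by donor and IFN-γ state (0.0107). CD163 was called in the fit of these 2 groups alone (0.0352). For both genes the highest adjusted p over the alternatives was 1. Of 25 inhibitory receptors of phagocytosis 7 fell and 0 rose (0 higher and 12 lower adjusted over the list alone; camera adjusted p = 1.5e-06, and adjusted p = 0.277 with an estimated correlation), among them SIGLEC10 at -0.74 ± 0.17 and PILRA at -0.42 ± 0.071. SIRPA, the receptor for CD47, had a log2 change of -0.17 ± 0.082 and was not called (adjusted p = 0.196). Of 24 complement genes 8 fell and 0 rose (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 1.46e-08, and adjusted p = 0.0368 with an estimated correlation). Among them were C1QC at -0.78 ± 0.17 and C3 at -0.67 ± 0.099. Of 41 lysosomal genes 17 fell and 1 rose (1 higher and 21 lower adjusted over the list alone; camera adjusted p = 6e-07, and adjusted p = 0.277 with an estimated correlation). Among them were the progranulin gene GRN at -0.51 ± 0.10 and HEXA at -0.35 ± 0.063.

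Of 23 cholesterol synthesis genes 8 fell and 0 rose (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 1.28e-08, and adjusted p = 0.136 with an estimated correlation), and DHCR7, a late enzyme of the pathway, had a log2 change of -0.98 ± 0.13. The largest falls under the named-gene rule were OLFML3, a secreted glycoprotein, at -1.62 ± 0.20, MS4A6A at -1.20 ± 0.27 and the Wnt receptor FZD2 at -1.11 ± 0.19. Next came the iron exporter SLC40A1 at -1.06 ± 0.21 and CD14 at -1.06 ± 0.18. The bile acid receptor GPBAR1 followed at -1.03 ± 0.24 and the transcription factor POU2F2 at -1.02 ± 0.19. Of 27 alternative activation and tissue-resident markers 8 fell and 2 rose (3 higher and 12 lower adjusted over the list alone; camera adjusted p = 0.00155, and adjusted p = 0.277 with an estimated correlation). The 17 monocyte markers held 4 lower and 0 higher (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.000239, and adjusted p = 0.134 with an estimated correlation), and the 6 measured NADPH oxidase genes 1 lower and 0 higher (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0177, and adjusted p = 0.277 with an estimated correlation).

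IFN-γ targets as a list did not pass with LCL161 alone: 1 of 34 rose and 2 fell (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.645). The member that rose was IDO1, which breaks down tryptophan, at 2.00 ± 0.64, from 23.5 to 92.1 CPM (adjusted p = 0.0476). CXCL9 had a log2 change of 0.00 ± 0.82, CXCL10 of -0.35 ± 0.78, the PD-L1 gene CD274 of 0.89 ± 0.36 and CD80 of 0.29 ± 0.22, and none was called (adjusted p = 0.999, 0.826, 0.117 and 0.441). Of 35 type I interferon-stimulated genes 0 rose and 1 fell (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.696 with an estimated correlation). MHC class I genes held 2 lower of 21 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.082) and MHC class II genes 1 lower of 20 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.088). Co-stimulation and checkpoint ligands held 6 higher and 1 lower of 21 (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0462, and adjusted p = 0.513 with an estimated correlation). Of 37 apoptosis and necroptosis genes 3 rose and 2 fell (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.908).

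Markers of other cell types moved in both directions. Whether macrophages gave these counts, here and below, was not tested. Granulocyte markers held 5 lower and 0 higher of 9, with a median of -0.47 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.00016, and adjusted p = 0.0368 with an estimated correlation). Among them were CSF3R at -0.47 ± 0.086, which monocytes also express, and CXCR2 at -0.87 ± 0.18; their share of counts went from 0.0193% to 0.0143%, lower in 8 of 8 donors (exact paired permutation p = 0.00781, 2-sided, and 0.0203 after adjustment over 52 tests). T and NK cell markers held 0 higher and 1 lower of 28 (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.168), with a share of 0.0189% in DMSO and 0.0208% in LCL161, higher in 7 of 8 donors (exact paired permutation p = 0.0234, and 0.042 after adjustment). The 5 measured platelet and erythroid markers held 2 higher and 0 lower (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0156, and adjusted p = 0.136 with an estimated correlation), with a share of 0.00445% in DMSO and 0.00697% in LCL161, higher in 7 of 8 donors (exact paired permutation p = 0.0234, and 0.042 after adjustment). The share of fibroblast and endothelial markers went from 0.0433% to 0.0349%, lower in 8 of 8 donors (exact paired permutation p = 0.00781, and 0.0203 after adjustment). The dendritic cell genes CCR7 and IL7R are also expressed by T cells. Mitochondrially encoded genes held 0 higher and 0 lower of 13 with a median of 0.15 (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0211, and adjusted p = 0.613 with an estimated correlation). Ribosomal protein genes held 3 higher and 0 lower of 36 (7 higher and 0 lower adjusted over the list alone; camera adjusted p = 5.18e-06, and adjusted p = 0.586 with an estimated correlation). The number of genes with a count above 0 rose by 567 ± 391 (SD, n = 8), higher in 8 of 8 donors (exact paired permutation p = 0.00781, and 0.0203 after adjustment).

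In all, LCL161 changed 1848 of 17841 genes, 857 higher and 991 lower, of which 96 rose and 60 fell by more than 2-fold. The count was 956 to 2472 with 1 donor left out and 1231 without the filter on low counts. It was 3662 with only the DMSO and LCL161 libraries in the fit. Against a minimum fold of 1.5 it was 41 (36 higher and 5 lower), and without the donor in the model 10. With upper-quartile factors 974 genes were higher and 940 lower. With 1 donor left out, the adjusted p reached 0.145 for IDO1, 0.121 for RELB, 0.0681 for BIRC2 and 0.0781 for FCGR1A. With all donors, IDO1 was not called with limma-voom (adjusted p = 0.0866) or without the filter on low counts (0.125). RELB (0.11) and FCGR1A (0.059) were not called without that filter either. CD274 (adjusted p = 0.00115) and XIAP (0.0384) were called in the fit of these 2 groups alone. Over the alternatives CD274 ranged from 4.39e-05 to 1 and XIAP from 0.0384 to 1.

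The comparison of IFN-γ with DMSO gives the response to the cytokine alone, the background against which the combination was read. IFN-γ raised its known targets many-fold, raised most antigen presentation and cell death genes, and lowered many genes of matrix remodelling and the cell cycle, while lipid handling genes moved both ways with more of them lower. None of these list calls held with an estimated correlation. IDO1 rose by 5.75 ± 0.75, from 23.5 to 754 CPM (n = 8, edgeR adjusted p = 1.83e-06). CD274 rose by 3.84 ± 0.40, the chemokines CXCL9 and CXCL10 by 4.08 ± 0.91 and 4.09 ± 0.84, and the Fc receptor FCGR1A by 2.22 ± 0.20. TNF rose by 1.51 ± 0.30, while IL1B had a log2 change of -1.22 ± 0.31 and was called lower. MERTK and CD163 had changes of -1.41 ± 0.22 and -0.95 ± 0.22, both called. In GRCh38, IDO1 lies on chromosome 8, 39902275 to 39928444, CD274 on chromosome 9, 5450503 to 5470566 and CXCL9 on chromosome 4, 76001275 to 76007488.

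All 34 measured IFN-γ core targets rose, with a median of 2.96 (34 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.92e-35, and adjusted p = 0.171 with an estimated correlation). They included the signalling inhibitor SOCS1 at 5.44 ± 0.67, the guanylate-binding protein GBP5 at 5.10 ± 0.53, APOL4 at 5.95 ± 0.74, ANKRD22 at 4.78 ± 0.65, SECTM1 at 3.22 ± 0.23, JAK2 at 2.15 ± 0.13 and IL18BP at 1.96 ± 0.15. CALHM6 rose by 5.36 ± 0.56. ENSG00000254287 (5.51 ± 0.60) is annotated antisense to IDO1 and ENSG00000237568 (4.79 ± 0.48) antisense to GBP5; as the strand setting of the counting is not given, their reads cannot be told from those of their partners. Of 35 type I interferon-stimulated genes 33 rose and 0 fell (34 higher and 0 lower adjusted over the list alone; camera adjusted p = 5.04e-25, and adjusted p = 0.292 with an estimated correlation). Among them were IFIT2 at 3.02 ± 0.28 and IFI35 at 2.09 ± 0.21. MHC class I presentation genes held 15 higher and 0 lower of 21 (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.31e-10, and adjusted p = 0.349 with an estimated correlation). Among them were the peptide transporter TAP1 at 2.63 ± 0.27 and PSMB10 at 1.66 ± 0.16. MHC class II genes held 18 higher and 0 lower of 20 (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.6e-07, and adjusted p = 0.528 with an estimated correlation). Among them were the transactivator CIITA at 1.95 ± 0.21, RFX5 at 0.93 ± 0.093 and HLA-DMB at 1.34 ± 0.19.

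Cell death genes rose with IFN-γ: 26 of 37 rose and 6 fell (26 higher and 7 lower adjusted over the list alone; camera adjusted p = 7.94e-09, and adjusted p = 0.143 with an estimated correlation). Among them were CASP8 at 0.72 ± 0.071 and the survival factor MCL1 at 0.93 ± 0.092. The death ligand TRAIL, encoded by TNFSF10, rose by 3.85 ± 0.39. Co-stimulation and checkpoint ligands held 13 higher and 2 lower of 21 (13 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000146, and adjusted p = 0.292 with an estimated correlation). Among them were CD40 at 2.38 ± 0.26, SLAMF7 at 2.21 ± 0.25 and CD80 at 1.49 ± 0.21. Canonical NF-kB genes held 17 higher and 2 lower of 28 (17 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000167, and adjusted p = 0.528 with an estimated correlation), and non-canonical NF-kB genes 6 and 3 of 17 (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.165). RELB rose by 0.66 ± 0.16, while NFKB2 had a log2 change of 0.26 ± 0.15, MAP3K14 of -0.05 ± 0.15, BIRC3 of 0.38 ± 0.24, BIRC2 of 0.06 ± 0.083 and XIAP of -0.15 ± 0.088, with adjusted p of 0.19, 0.804, 0.212, 0.568 and 0.165. BIRC3 was higher in 8 of 8 donors, and BIRC3 and NFKB2 were called in the fit of these 2 groups alone (adjusted p = 0.00185 and 0.0462, and up to 1 over the alternatives). The mature dendritic cell list held 6 higher and 10 lower of 26 (7 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.856).

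Phagocytic and efferocytic receptors moved in both directions: 22 of 42 fell and 8 rose (9 higher and 23 lower adjusted over the list alone; camera adjusted p = 0.0347, and adjusted p = 0.66 with an estimated correlation). The oxidised lipoprotein receptor OLR1 had a change of -1.85 ± 0.18, the scavenger receptor COLEC12 one of -2.23 ± 0.21 and SCARF1 one of 1.30 ± 0.14. CD47, the ligand of SIRPA, rose by 1.09 ± 0.11, while SIRPA had a log2 change of -0.02 ± 0.082 and MRC1 of -0.48 ± 0.22 (adjusted p = 0.858 and 0.0788). MRC1 was called with DESeq2 (adjusted p = 0.0453) and with 1 donor left out (0.0422), with a highest adjusted p of 1 over the alternatives. Inhibitory receptors of phagocytosis held 9 higher and 6 lower of 25 (10 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.246). Complement genes held 12 higher and 7 lower of 24 (12 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.191): the near-identical gene copies C4A and C4B, whose reads cannot be told apart with certainty, rose by 4.02 ± 0.40 and 4.24 ± 0.41, while the receptor CR1 had a log2 change of -1.78 ± 0.19 and was called lower. Matrix remodelling genes held 15 lower and 1 higher of 24 (1 higher and 16 lower adjusted over the list alone; camera adjusted p = 0.00121, and adjusted p = 0.528 with an estimated correlation), and TIMP3, an inhibitor of matrix proteases, had a log2 change of -1.29 ± 0.18. Lipid handling genes held 13 lower and 5 higher of 27 (7 higher and 13 lower adjusted over the list alone; camera adjusted p = 0.0347, and adjusted p = 0.66 with an estimated correlation). Among them were the lipase LPL at -1.78 ± 0.15 and the nuclear receptor PPARG at -1.07 ± 0.13. Cell cycle genes held 15 lower and 0 higher of 29 (0 higher and 18 lower adjusted over the list alone; camera adjusted p = 0.00975, and adjusted p = 0.694 with an estimated correlation). Among them were CCNE2 at -1.31 ± 0.34 and PLK1 at -1.19 ± 0.36. PLK1 was not called with limma-voom (adjusted p = 0.0854).

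The largest falls under the named-gene rule were TMEM119 at -2.46 ± 0.37, NOTCH3 at -2.33 ± 0.28, the protease HTRA1 at -2.28 ± 0.25 and TRIM54 at -2.26 ± 0.26. Next came COLEC12 at -2.23 ± 0.21 and GPR34 at -2.02 ± 0.17. The selenium carrier SELENOP followed at -1.92 ± 0.33 with CCDC152, which overlaps it on the opposite strand, at -1.93 ± 0.32. Mitochondrially encoded genes held 9 lower and 0 higher of 13 (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.0347, and adjusted p = 0.694 with an estimated correlation), and their share of counts was 2.69% ± 0.811 (SD, n = 8) in DMSO and 2.30% ± 0.798 in IFN-γ (exact paired permutation p = 0.0312, 2-sided, 0.0492 after Benjamini-Hochberg adjustment over 52 composition tests). Ribosomal protein genes held 17 lower and 0 higher of 36 (0 higher and 19 lower adjusted over the list alone; camera adjusted p = 0.0118, and adjusted p = 0.77 with an estimated correlation). In all, 7393 of 17841 genes changed, 3522 higher and 3871 lower, of which 703 rose and 675 fell by more than 2-fold. No list call of this comparison held with an estimated correlation, while fry kept 15 of 15 in the same direction. Granulocyte markers held 5 lower and 0 higher of 9 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0999). The shares of granulocyte, platelet and erythroid, B and plasma cell, and fibroblast and endothelial markers were each lower with IFN-γ in 8 of 8 donors, with mean changes of -0.00284, -0.00193, -0.000982 and -0.0102 percentage points (exact paired permutation p = 0.00781, and 0.0203 after adjustment, for each). Without the donor in the model the count was 2467, and against a minimum fold of 1.5 it was 1331.

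The comparison of LCL161 plus IFN-γ with IFN-γ asks what the SMAC mimetic changed in macrophages that were also receiving the cytokine. Most NF-kB and dendritic cell genes that LCL161 raised in resting cells were also called higher here, CD14 and other uptake genes fell, and mitochondrially encoded and ribosomal protein transcripts rose. RELB and IDO1 were among the exceptions (adjusted p = 0.0599 and 0.493). Both were higher in 8 of 8 donors and were called in the fit of these 2 groups alone (0.00744 and 0.00042) and with the block by donor and IFN-γ state (0.0144 and 0.0337), with a highest adjusted p of 1 over the alternatives. The calls of the canonical NF-kB, phagocytic receptor, mitochondrially encoded and ribosomal protein lists were lost with an estimated correlation (adjusted p = 0.0826, 0.124, 0.166 and 0.336). BIRC3 rose by 2.63 ± 0.24, from 18.9 to 113 CPM (n = 8, edgeR adjusted p = 2.02e-07). TRAF1 rose by 2.72 ± 0.28, CCR7 by 2.16 ± 0.24, IL7R by 2.13 ± 0.25 and CCL17 by 4.02 ± 0.33. CD14 had a change of -1.17 ± 0.18, from 827 to 420 CPM, and OLFML3 one of -1.75 ± 0.20, both lower in 8 of 8 donors. In GRCh38, CCR7 lies on chromosome 17, 40553769 to 40565472 and OLFML3 on chromosome 1, 113979391 to 114035572.

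Non-canonical NF-kB genes held 10 higher and 3 lower of 17 (11 higher and 4 lower adjusted over the list alone; camera adjusted p = 4.93e-07, and adjusted p = 0.0315 with an estimated correlation). Among them were MAP3K14 at 1.71 ± 0.15, NFKB2 at 1.17 ± 0.16 and the chemokine CCL19 at 2.08 ± 0.30. RELB had a log2 change of 0.40 ± 0.16 and was not called (adjusted p = 0.0599). All 3 IAP genes rose (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.24e-05, and adjusted p = 0.0428 with an estimated correlation). Among them were BIRC2 at 0.39 ± 0.083 and XIAP at 0.35 ± 0.088. Canonical NF-kB genes held 16 higher and 0 lower of 28 (18 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.79e-15, and adjusted p = 0.0826 with an estimated correlation). Among them were NFKBIA at 1.62 ± 0.17, CD83 at 1.26 ± 0.14 and CFLAR at 0.58 ± 0.078. Of 26 mature dendritic cell genes 15 rose and 0 fell (17 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.19e-14, and adjusted p = 0.0315 with an estimated correlation), and LAMP3 rose by 1.84 ± 0.30. CYP27B1 rose by 2.17 ± 0.23 and TNFRSF9 by 1.96 ± 0.24. Chemokines held 10 higher and 1 lower of 27 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.22e-05, and adjusted p = 0.277 with an estimated correlation). Among them were CCL3 at 1.39 ± 0.24, CXCL11 at 1.86 ± 0.49 and CXCL9 at 2.24 ± 0.76 (adjusted p = 0.0345).

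In the fit of all groups, few IFN-γ targets were called against IFN-γ alone. Of 34 core targets 2 rose and 1 fell (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.71, a lower direction although the mean of the list was 0.09 and its median -0.04). CXCL10 had a log2 change of 1.47 ± 0.71, IDO1 of 0.61 ± 0.60, CD274 of 0.21 ± 0.34 and CD80 of 0.38 ± 0.20, with adjusted p of 0.136, 0.493, 0.696 and 0.172. In the edgeR fit of these 2 groups alone IDO1 (adjusted p = 0.00042), CXCL10 (0.00398), CD80 (0.0242) and CD274 (0.0481) were called higher, and FCGR1A (0.0163) lower. TNF had a log2 change of -0.11 ± 0.28 and IL1B of 0.66 ± 0.31 (adjusted p = 0.81 and 0.128). Type I interferon-stimulated genes held 3 lower and 0 higher of 35 (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.692 with an estimated correlation). Among them were IFIT1 at -0.78 ± 0.21 and SIGLEC1 at -0.73 ± 0.15.

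Of 42 phagocytic and efferocytic receptors 19 fell and 1 rose (1 higher and 21 lower adjusted over the list alone; camera adjusted p = 3.25e-07, and adjusted p = 0.124 with an estimated correlation). Among them were STAB1 at -1.14 ± 0.17, FCGR2A at -0.83 ± 0.13, CD93 at -1.60 ± 0.32, VSIG4 at -0.77 ± 0.15 and CD163 at -0.62 ± 0.22 (adjusted p = 0.042). MERTK had a log2 change of -0.35 ± 0.22, FCGR1A of -0.39 ± 0.18 and MRC1 of -0.54 ± 0.21, and none of these was called (adjusted p = 0.266, 0.122 and 0.0698). Of 25 inhibitory receptors 14 fell and 0 rose (0 higher and 15 lower adjusted over the list alone; camera adjusted p = 3.25e-07, and adjusted p = 0.269 with an estimated correlation). Among them were SIGLEC11 at -1.15 ± 0.23, PILRA at -0.56 ± 0.072 and SIRPA at -0.23 ± 0.082 (adjusted p = 0.0415). Complement genes held 8 lower and 0 higher of 24 (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.00124, and adjusted p = 0.277 with an estimated correlation). C3AR1 was lower at -0.89 ± 0.16. Lysosomal genes held 17 lower and 4 higher of 41 (4 higher and 19 lower adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.465 with an estimated correlation), and GRN was lower at -0.57 ± 0.10. Cholesterol synthesis genes held 16 lower and 0 higher of 23 (0 higher and 16 lower adjusted over the list alone; camera adjusted p = 5.89e-11, and adjusted p = 0.124 with an estimated correlation). Among them were DHCR7 at -1.20 ± 0.13 and CYP51A1 at -0.64 ± 0.093. Further falls under the named-gene rule were the lysophosphatidic acid receptor LPAR5 at -1.30 ± 0.17, the adenosine receptor ADORA3 at -1.28 ± 0.34, LRRC4 at -1.34 ± 0.27, ZNF467 at -1.22 ± 0.17 and FZD2 at -1.20 ± 0.18.

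All 13 mitochondrially encoded genes rose (13 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.81e-12, and adjusted p = 0.166 with an estimated correlation). Among them were MT-CO3 at 0.70 ± 0.10 and MT-CYB at 0.67 ± 0.12. Their share of counts, a usual measure of RNA quality, went from 2.30% ± 0.798 (SD, n = 8) in IFN-γ to 3.42% ± 1.1 in the combination, higher in 8 of 8 donors (exact paired permutation p = 0.00781, 2-sided, the smallest that 8 pairs allow, and 0.0203 after adjustment over 52 tests). Ribosomal protein genes held 30 higher and 0 lower of 36 (33 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.3e-12, and adjusted p = 0.336 with an estimated correlation). Among them were RPS6 at 0.52 ± 0.11 and RPL5 at 0.45 ± 0.097. In parallel, 17 of 36 nuclear genes of oxidative phosphorylation rose while 2 fell (21 higher and 2 lower adjusted over the list alone; camera adjusted p = 5.46e-05, and adjusted p = 0.447 with an estimated correlation). T and NK cell markers held 8 higher and 1 lower of 28 (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00041, and adjusted p = 0.336 with an estimated correlation). Among them were CD2 at 1.00 ± 0.18, GNLY at 1.05 ± 0.20 and TRBC2 at 0.76 ± 0.17; their share of counts was 0.0187% in IFN-γ and 0.0232% in the combination, higher in 6 of 8 donors (exact paired permutation p = 0.0312, and 0.0492 after adjustment). Granulocyte markers held 5 lower and 0 higher of 9 (0 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0194, and adjusted p = 0.193 with an estimated correlation). Fibroblast and endothelial markers had a lower share of counts in 8 of 8 donors (exact paired permutation p = 0.00781, and 0.0203 after adjustment). Granulocyte and B and plasma cell markers had lower shares in 7 of 8 donors, and platelet and erythroid markers a higher one in 7 of 8 (adjusted permutation p = 0.0325, 0.042 and 0.0325). The share of counts in protein-coding genes changed by -0.345 ± 0.384 percentage points (SD, n = 8), lower in 8 of 8 donors. For that share, 1 library of the combination lay far from the others of its group. The number of genes with a count above 0 rose by 649 ± 680, higher in 8 of 8 donors (exact paired permutation p = 0.00781 for both, and 0.0203 after adjustment).

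In all, 4457 of 17841 genes changed, 2214 higher and 2243 lower, of which 231 rose and 112 fell by more than 2-fold. The count was 2877 to 5100 with 1 donor left out, 119 against a minimum fold of 1.5 and 107 without the donor in the model. With 1 donor left out, the adjusted p reached 0.109 for CXCL9, 0.142 for CD163 and 0.191 for SIRPA. In the fit of these 2 groups alone, IDO1 (adjusted p = 0.00042), CXCL10 (0.00398), MRC1 (0.00535), RELB (0.00744), FCGR1A (0.0163), CD80 (0.0242), IL1B (0.0272) and CD274 (0.0481) were called. In that fit CD163 (0.0944) and SIRPA (0.0845) were not called. All of the first 8 except CD274 were also called with the block by donor and IFN-γ state. DESeq2 called MRC1 (0.0379) and RELB (0.042), limma-voom MRC1 (0.0383) and the fit with upper-quartile factors RELB (0.0465). Over the alternatives the lowest adjusted p of these 8 genes, in the same order, was 0.00042, 0.000933, 0.000938, 0.00744, 0.012, 0.0197, 0.0095 and 0.0481, and the highest was 1 for each. Among lists, the IAP, non-canonical NF-kB and mature dendritic cell calls held with an estimated correlation; with LCL161 alone these 3 held together with canonical NF-kB, phagocytic receptors, complement and granulocyte markers. With the block by donor and IFN-γ state and an estimated correlation, all of these calls were lost except non-canonical NF-kB with LCL161 alone (adjusted p = 0.0298). The IAP, non-canonical NF-kB and mature dendritic cell lists then had an adjusted p of 0.121, 0.0939 and 0.0939 in the combination against IFN-γ. These lists are not separate sets of genes. BIRC3 is in all 3 and in the canonical NF-kB list, RELB in the non-canonical and dendritic cell lists, and TRAF1 in the canonical and dendritic cell lists.

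**Figure D2:**
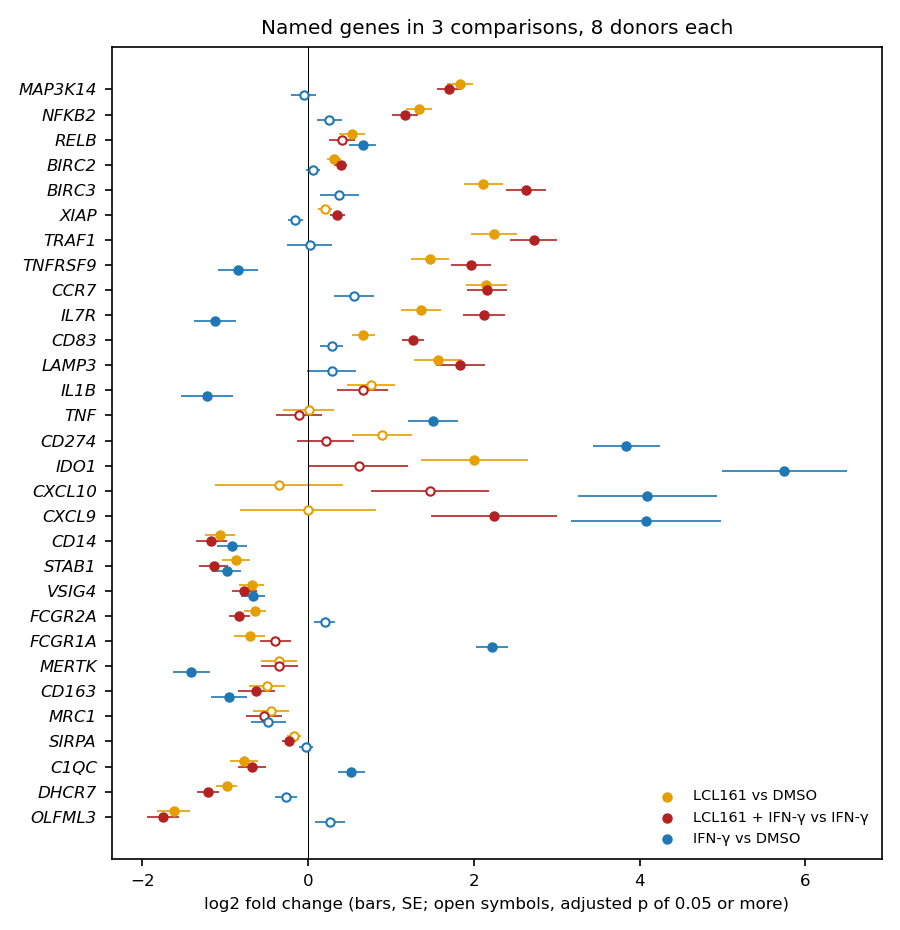
Log2 fold change (x axis) of selected named genes in LCL161 vs DMSO, LCL161 plus IFN-γ vs IFN-γ and IFN-γ vs DMSO, 8 donors each. Bars are the standard error from the fit of all groups, and symbols are open where the adjusted p was 0.05 or more. MAP3K14, BIRC3, TRAF1 and CCR7 lie right of 0 in both comparisons of LCL161, and of the genes drawn IDO1, CXCL9, CXCL10 and CD274 lie farthest right with IFN-γ.

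**Figure D3:**
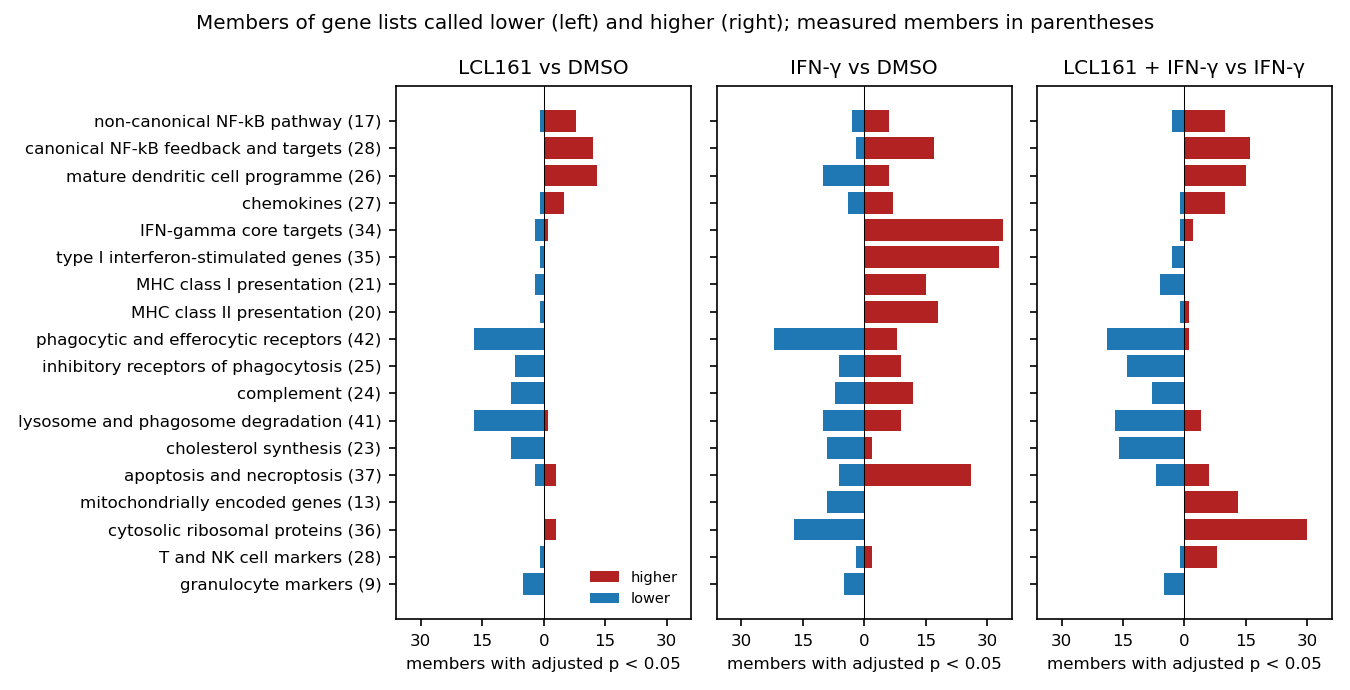
Number of members of the gene lists with an adjusted p below 0.05 (x axis), lower to the left and higher to the right, in 3 comparisons, with the number of measured members in parentheses. IFN-γ core targets were all higher with IFN-γ, and the 13 mitochondrially encoded genes were all higher with the combination against IFN-γ.

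The combination against DMSO gives the joint change under both treatments. IDO1 rose by 6.36 ± 0.77, from 23.5 to 1196 CPM, and CXCL9 by 6.32 ± 0.97, from 7.01 to 667 CPM (n = 8, edgeR adjusted p = 3.9e-07 and 1.03e-05). BIRC3 rose by 3.01 ± 0.24, MAP3K14 by 1.65 ± 0.15, NFKB2 by 1.43 ± 0.16, CD274 by 4.05 ± 0.40 and TNF by 1.40 ± 0.30. CXCL10, APOL4, CALHM6, ANKRD22, GBP5 and ENSG00000254287 rose by 5.57 ± 0.89, 5.65 ± 0.74, 5.33 ± 0.56, 5.26 ± 0.66, 4.99 ± 0.52 and 6.18 ± 0.61. The largest falls under the named-gene rule were CD93 at -3.13 ± 0.31, ADORA3 at -2.95 ± 0.34, CCDC152 at -2.94 ± 0.34 and SELENOP at -2.93 ± 0.35. Next came GPR34 at -2.82 ± 0.17, COLEC12 at -2.79 ± 0.22, the toll-like receptor homologue CD180 at -2.77 ± 0.25 and NOTCH3 at -2.39 ± 0.28. MERTK had a log2 change of -1.75 ± 0.23, CD163 of -1.57 ± 0.23 and MRC1 of -1.01 ± 0.22, all called lower, and FCGR1A of 1.83 ± 0.19.

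By list, 24 of 28 canonical NF-kB genes rose (24 higher and 0 lower adjusted over the list alone; camera adjusted p = 6.51e-16, and adjusted p = 0.112 with an estimated correlation), 34 of 34 IFN-γ core targets rose (34 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.02e-25, and adjusted p = 0.131 with an estimated correlation), and 29 of 42 phagocytic receptors fell while 8 rose (8 higher and 30 lower adjusted over the list alone; camera adjusted p = 8.82e-07, and adjusted p = 0.125 with an estimated correlation). Cholesterol synthesis genes held 18 lower and 1 higher of 23 (1 higher and 18 lower adjusted over the list alone; camera adjusted p = 7.44e-08, and adjusted p = 0.187 with an estimated correlation). Markers of other cell types moved as well. T and NK cell markers held 16 higher and 1 lower of 28 (18 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.533 with an estimated correlation). Granulocyte markers held 6 lower and 0 higher of 9, with a median of -0.80 (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00268, and adjusted p = 0.112 with an estimated correlation). Their share of counts had a change of -0.00718 ± 0.0026 percentage points (SD, n = 8) and that of fibroblast and endothelial markers one of -0.0191 ± 0.00678, both lower in 8 of 8 donors (exact paired permutation p = 0.00781, and 0.0203 after adjustment). In all, 9200 of 17841 genes changed, 4573 higher and 4627 lower, 866 and 916 of them by more than 2-fold. None of the 21 list calls held with an estimated correlation, while fry kept 21 of 21 in the same direction. Without the donor in the model the count was 4029, and against a minimum fold of 1.5 it was 1888.

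The comparison of the combination with LCL161 gives the IFN-γ response in cells that also received the SMAC mimetic. CXCL9 rose by 6.31 ± 0.97, CXCL10 by 5.92 ± 0.91, APOL4 by 5.88 ± 0.74 and PLAAT4, a phospholipase, by 4.94 ± 0.44 (n = 8, edgeR adjusted p = 1.57e-05, 1.44e-05, 1.2e-06 and 8.38e-09). CD180 had a change of -2.23 ± 0.24, CD93 of -2.19 ± 0.31 and XYLT1 of -2.04 ± 0.22. BIRC3 rose by 0.90 ± 0.22 and RELB by 0.54 ± 0.16, whereas NFKB2 and MAP3K14 had a log2 change of 0.08 ± 0.15 and -0.18 ± 0.14 (adjusted p = 0.691 and 0.321). MAP3K14 was called lower in the fit of these 2 groups alone (adjusted p = 0.0463, and up to 1 over the alternatives). All 34 IFN-γ core targets rose (34 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.13e-35, and adjusted p = 0.18 with an estimated correlation). Among markers of other cell types, T and NK cell markers held 9 higher and 1 lower of 28 with a median of 0.41 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0727). Fibroblast and endothelial markers held 1 higher and 4 lower of 8 with a median of -0.90 (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0808). Granulocyte markers held 1 higher and 3 lower of 9 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.16), and platelet and erythroid markers 0 higher and 2 lower of 5 (0 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.149). In all, 7474 genes changed, 3575 higher and 3899 lower; without the donor in the model the count was 2406, and against a minimum fold of 1.5 it was 1243. None of the 15 list calls held with an estimated correlation, while fry kept 15 of 15 in the same direction.

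The direct comparison of LCL161 with IFN-γ separates the single treatments. TMEM119 was higher with LCL161 by 2.94 ± 0.37, TRIM54 by 2.58 ± 0.26, IL7R by 2.49 ± 0.25, the lipoxygenase ALOX15B by 2.38 ± 0.24, TNFRSF9 by 2.32 ± 0.24, the oxysterol receptor GPR183 by 2.22 ± 0.29 and TRAF1 by 2.22 ± 0.28 (n = 8, edgeR adjusted p from 1.71e-08 to 1.15e-06). MAP3K14 and NFKB2 were higher with LCL161 by 1.89 ± 0.15 and 1.09 ± 0.16, IL1B by 1.98 ± 0.31 and MERTK by 1.06 ± 0.22. Lower with LCL161 were APOL4 at -6.18 ± 0.75, GBP5 at -5.47 ± 0.53, ASCL2 at -4.51 ± 0.36, ETV7 at -4.47 ± 0.54, CD274 at -2.95 ± 0.38, FCGR1A at -2.93 ± 0.20 and TNF at -1.50 ± 0.30. The mature dendritic cell list held 18 higher and 5 lower of 26 (19 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0057, and adjusted p = 0.482 with an estimated correlation), platelet and erythroid markers 3 higher and 0 lower of 5 (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0108, and adjusted p = 0.233 with an estimated correlation), and IFN-γ core targets 34 lower of 34 (0 higher and 34 lower adjusted over the list alone; camera adjusted p = 1.21e-29, and adjusted p = 0.233 with an estimated correlation). Mitochondrially encoded genes held 13 higher and 0 lower of 13 with a median of 0.48 (13 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00163, and adjusted p = 0.581 with an estimated correlation). Ribosomal protein genes held 27 higher and 0 lower of 36 with a median of 0.36 (28 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.42e-06, and adjusted p = 0.586 with an estimated correlation). In all, 8611 genes differed, 4563 higher and 4048 lower; without the donor in the model the count was 3332, and against a minimum fold of 1.5 it was 1768. None of the 19 list calls held with an estimated correlation, while fry kept 19 of 19 in the same direction.

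The interaction tests whether the LCL161 effect differed with IFN-γ present. The edgeR test called 0 of 17841 genes, with 673 at an unadjusted p below 0.05 against 892 from chance and a smallest adjusted p of 0.415. With the block by donor and IFN-γ state it also called 0, with 1095 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0775, and with no filter on low counts 0, with 998 and 0.113. limma-voom called 0 and DESeq2 called 2, both with an adjusted p of 0.0142 and, over the other alternatives, of up to 1. These were GABBR1, with an edgeR interaction of 2.02 ± 0.44, and IER3-AS1, with 0.91 ± 0.18; both are named because the count was small, after their values were seen, and both share exonic bases with another gene, UBD for GABBR1 and IER3 for IER3-AS1. GABBR1 stood at 1.74 CPM in DMSO, 2.81 in LCL161, 8.89 in IFN-γ and 59.0 in the combination. CXCL9 had an interaction of 2.24 ± 1.12, CXCL10 of 1.82 ± 1.04, BIRC3 of 0.52 ± 0.32, IDO1 of -1.40 ± 0.86 and CD274 of -0.68 ± 0.50, all with an adjusted p of 1. The interaction of CXCL9 was above 0 in 8 of 8 donors and that of CD274 below 0 in 8 of 8. Over the alternatives the lowest adjusted p was 0.34 for CXCL9, 0.416 for CXCL10, 0.872 for BIRC3, 0.505 for IDO1 and 0.221 for CD274.

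By list, camera with the preset correlation called 10 lists for the interaction. Mitochondrially encoded genes had a median interaction of 0.42 (camera adjusted p = 2.57e-17, and adjusted p = 0.375 with an estimated correlation; 0 called over all genes, and 11 higher and 0 lower adjusted over the list alone). The share of mitochondrially encoded counts had an interaction of 0.743 ± 0.901 percentage points (SD, n = 8; exact paired permutation p = 0.0391, and 0.122 after adjustment over its family). Chemokines had a median interaction of 0.42 (camera adjusted p = 3.51e-05, and adjusted p = 0.587 with an estimated correlation), mature dendritic cell genes of 0.21 (camera adjusted p = 0.000743, and adjusted p = 0.587 with an estimated correlation), ribosomal protein genes of 0.14 (camera adjusted p = 8.78e-08, and adjusted p = 0.928 with an estimated correlation), T and NK cell markers of 0.25 (camera adjusted p = 0.000165, and adjusted p = 0.587 with an estimated correlation) and cholesterol synthesis genes of -0.13 (camera adjusted p = 0.00286, and adjusted p = 0.928 with an estimated correlation). None of the 10 list calls held with an estimated correlation, and fry called 0 lists.

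Most genes called with LCL161 alone were also called with IFN-γ present. Of the 1848 genes called with LCL161 alone, 1477 were also called in the same direction in the presence of IFN-γ and 0 in the opposite direction, and 99.2% kept their sign, against 78.2% over all 17841 genes. Of the 4457 genes called with IFN-γ present, 2980 were not called without it; the interaction called 0 genes. These comparisons share no libraries. Independent lists of these sizes would share 106.4 genes higher and 124.6 lower, against 661 and 816 observed. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.783. The IFN-γ response behaved alike: 5760 of 7393 genes were called in the same direction with LCL161 present and 2 in the opposite direction, with r = 0.936 across genes.

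**Figure D4:**
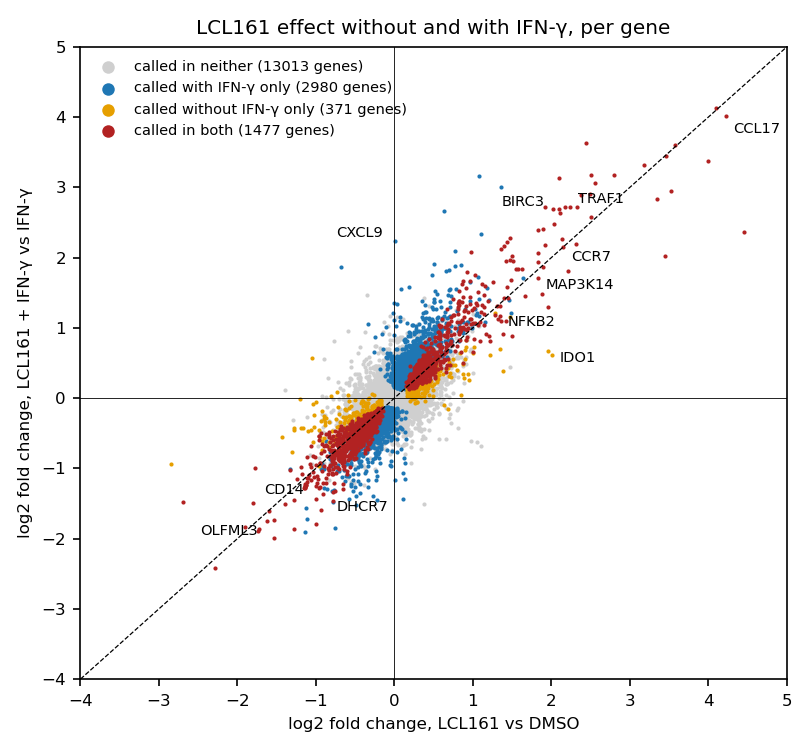
Log2 fold change of LCL161 vs DMSO (x axis) and of LCL161 plus IFN-γ vs IFN-γ (y axis) for 17841 genes, 1 point per gene, coloured by the comparison in which the gene was called, with the line of equal change dashed. The 1477 genes called in both (red) lie in the lower left or the upper right.

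The responses to LCL161 and to IFN-γ, both measured against the same DMSO libraries, shared more lower genes than independent lists would, and about as many higher genes. Of the genes higher with LCL161 and with IFN-γ, 176 were shared, against 169.2 for independent lists of these sizes, and of the lower genes 343 were shared, against 215. In opposite directions, 170 genes were higher with LCL161 and lower with IFN-γ, against 185.9, and 194 lower with LCL161 and higher with IFN-γ, against 195.6. With disjoint sets of 4 donors for the comparisons, the shared genes were 0 higher and 3 lower in one arrangement and 36 higher and 80 lower in the other, against 1.7, 2.2, 52 and 37.8 for independent lists. Across genes r was 0.055, against 0.081 for simulated unchanged groups against the same controls and 0.015 as the median over disjoint sets of 4 donors (-0.048 to 0.079); the covariance was 0.00902 observed, 0.0011 simulated and 0.00276 as that median. Simulated unchanged groups shared 0 calls in 3 fits; since groups without effects give almost no calls, this is no background for the overlap.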

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

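No test in this part was chosen after the result was seen, but some of its composition measures were not in the plan set beforehand. In each of 277 groups of 8 values, the gap between the farthest value and its nearest neighbour was divided by the group's range; 19 groups exceeded Dixon's critical value, where chance flags about 1 in 20 and 13.8 were expected. No direction or cause was tested for any of them.

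A library far from the others of its group was found for 4 of 52 composition measures: the share of CD3 and T cell receptor transcripts in LCL161 (0.528 of the range), and the share of protein-coding genes in IFN-γ (0.544), LCL161 (0.555) and the combination (0.666). For 15 of 225 gene comparisons, 1 donor's difference lay far from those of the others. With LCL161 against DMSO these were the chemokine gene CXCL9 (0.656), MERTK (0.595) and CXCR2 (0.588). With IFN-γ against DMSO they were IDO1 (0.595), CXCL10 (0.571) and CASP8 (0.55). With the combination against IFN-γ they were CYP27B1 (0.624), CXCL10 (0.611), MERTK (0.586) and CD80 (0.562). With the combination against DMSO they were NOTCH3 (0.711), MERTK (0.641), IDO1 (0.596) and ADORA3 (0.58), and for the interaction BIRC3 (0.656). No named gene had LCL161 effects of opposite sign in every donor with and without IFN-γ.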

How the results depend on the processing

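The block by donor and IFN-γ state was chosen after the data were seen; the other alternatives were set before. Counts of changed genes are given in the order LCL161, IFN-γ and the combination against DMSO, the combination against IFN-γ and against LCL161, and LCL161 against IFN-γ. Without the replicate block they were 10, 2467, 4029, 107, 2406 and 3332, since the spread between donors then enters the error. Against a fold of 1.5 they were 41, 1331, 1888, 119, 1243 and 1768, since smaller changes no longer count. For LCL161 against DMSO the count was 1231 with no filter on low counts and 3662 with only the groups compared; the cause was not tested. Leaving out 1 donor gave 956 to 2472 for LCL161 against DMSO and 2877 to 5100 for the combination against IFN-γ. DESeq2 called 2 interactions. The other counts stayed within 1.5 times the reported ones. Genes shared by LCL161 and IFN-γ from disjoint sets of 4 donors, with fewer libraries, were 0 or 36 higher and 3 or 80 lower. In the same order and then for the interaction, lists called with an estimated correlation were 7, 0, 0, 3, 0, 0 and 0. With fry, 29 lists were called for IFN-γ against DMSO, 29 for the combination against LCL161 and 0 for the interaction. Of the list calls of the main test, fry kept 16 of 21 for LCL161 against DMSO and 17 of 18 for the combination against IFN-γ. It kept every call for IFN-γ and the combination against DMSO, the combination against LCL161, and LCL161 against IFN-γ. Unlike camera, fry does not compare a list with other genes. Without the replicate block 3 interaction lists were called. With the block by donor and IFN-γ state and an estimated correlation, 1 list was called for LCL161 against DMSO, 0 for the combination against IFN-γ and 0 for the interaction; the cause was not tested. Of 225 named gene comparisons, 89 calls were lost without the replicate block, 64 against a fold of 1.5, 6 with no filter and 2 with limma-voom, while DESeq2 gained 5 and limma-voom and upper-quartile factors 1 each. With only the groups compared 16 calls of 218 were gained and 2 lost. With the block by donor and IFN-γ state 10 of 112 were gained and 1 lost. Over the fits without 1 donor, 27 calls were lost and 6 gained of 1800 results. For these alternatives 0 called values changed sign. In the simulated data 58% of 1.5-fold changes were called. Depth was not varied there, and far fewer genes were changed than were called in these data. No effect of IFN-γ was simulated either.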

Other observations

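The tests of explanations in this part were chosen after the result was seen, except the first test of transcript length and the label splits other than those for LCL161 against DMSO and the interaction. SLC7A11, the cystine transporter and a target of the oxidative stress factor NRF2, rose with LCL161 by 0.82 ± 0.14 without and 1.32 ± 0.15 with IFN-γ. NRF2 genes held 3 higher and 0 lower of 17 with LCL161 (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00816), 4 and 8 with IFN-γ (4 higher and 9 lower adjusted over the list alone; adjusted p = 0.0347), and 6 and 0 with the combination against IFN-γ (8 higher and 0 lower adjusted over the list alone; adjusted p = 0.000268). With an estimated correlation these were 0.46, 0.66 and 0.277. Metallothionein and zinc transport genes held 0 higher and 4 lower of 11 with LCL161 (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.00816), 3 and 4 with IFN-γ (3 higher and 4 lower adjusted over the list alone; adjusted p = 0.952), and 0 and 2 with the combination against IFN-γ (0 higher and 1 lower adjusted over the list alone; adjusted p = 0.0971). With an estimated correlation the first was 0.302. Osteoclast genes held 2 higher and 1 lower of 15 with LCL161 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.385), 1 and 9 with IFN-γ (1 higher and 10 lower adjusted over the list alone; adjusted p = 0.0118), and 4 and 2 with the combination against IFN-γ (4 higher and 3 lower adjusted over the list alone; adjusted p = 0.529). With an estimated correlation the second was 0.528. Tryptophan and arginine metabolism genes held 4 higher and 1 lower of 16 with LCL161 (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.256), 7 and 3 with IFN-γ (7 higher and 4 lower adjusted over the list alone; adjusted p = 0.163), and 4 and 2 with the combination against IFN-γ (6 higher and 3 lower adjusted over the list alone; adjusted p = 0.112). Glycolysis and hypoxia genes held 0 higher and 1 lower of 30 with LCL161 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.639), 4 and 5 with IFN-γ (4 higher and 5 lower adjusted over the list alone; adjusted p = 0.971), and 2 and 3 with the combination against IFN-γ (2 higher and 3 lower adjusted over the list alone; adjusted p = 0.793). The glycolysis list had a median of 0.02 and a mean of 0.01 with IFN-γ while the test pointed lower.

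Phagocytic signalling and actin genes held 3 higher and 6 lower of 43 with LCL161 (3 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.134), 11 and 3 with IFN-γ (11 higher and 3 lower adjusted over the list alone; adjusted p = 0.124), and 3 and 14 with the combination against IFN-γ (3 higher and 14 lower adjusted over the list alone; adjusted p = 0.0662). Migration and adhesion receptors held 2 higher and 5 lower of 25 with LCL161 (2 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0979), 8 and 9 with IFN-γ (9 higher and 10 lower adjusted over the list alone; adjusted p = 0.952), and 3 and 10 with the combination against IFN-γ (5 higher and 10 lower adjusted over the list alone; adjusted p = 0.104). The migration list had a median of -0.18 and a mean of 0.03 with the combination against IFN-γ, and of -0.03 and 0.08 with IFN-γ. Stress response genes held 0 higher and 1 lower of 23 with LCL161 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.646), 10 and 6 with IFN-γ (11 higher and 6 lower adjusted over the list alone; adjusted p = 0.191), and 2 and 3 with the combination against IFN-γ (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.482). Heat shock genes held 1 higher and 0 lower of 13 with LCL161 (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0847), 1 and 4 with IFN-γ (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.49), and 2 and 0 with the combination against IFN-γ (1 higher and 0 lower adjusted over the list alone; adjusted p = 0.196). Immediate early genes held 2 higher and 1 lower of 21 with LCL161 (3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.186), 7 and 4 with IFN-γ (7 higher and 5 lower adjusted over the list alone; adjusted p = 0.183), and 6 and 2 with the combination against IFN-γ (6 higher and 3 lower adjusted over the list alone; adjusted p = 0.354). B and plasma cell markers held 0 higher and 0 lower of 9 with LCL161 (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.35), 2 and 1 with IFN-γ (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.49), and 1 and 1 with the combination against IFN-γ (1 higher and 2 lower adjusted over the list alone; adjusted p = 0.196). Fibroblast and endothelial markers held 1 higher and 1 lower of 8 with LCL161 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.751), 1 and 3 with IFN-γ (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.592), and 1 and 2 with the combination against IFN-γ (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.0548). The fibroblast list had a median of -0.16 and a mean of 0.3 with LCL161, the TNF family list of -0.14 and 0.04 with IFN-γ, and the apoptosis list of 0.02 and -0.02 with LCL161. The medians of the actin, glycolysis, oxidative phosphorylation and tryptophan lists with IFN-γ changed sign under another scaling.

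The comparison of LCL161 with its control called 2.41 times as many genes with IFN-γ as without it. In fits of only the groups compared the ratio was 1.09, as would be seen if a pooled estimate of the spread gave much of the difference. With the block by donor and IFN-γ state, a fit that also pools the spread over all groups, the ratio was 2.05. Library totals argue against depth, with a ratio of 0.979 ± 0.0958 (SD, n = 8). Whether the effects were larger cannot be told apart from no difference: over the 1477 genes called in both, the mean directed change was 0.59 with and 0.52 without IFN-γ (difference 0.07 ± 0.12, larger in 5 of 8 donors, exact paired permutation p = 0.141). The bound for this last test was revised after its result was seen.

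Mature dendritic cell genes such as CCR7 were higher with LCL161. More T cells were argued against, since summed CD3 and T cell receptor transcripts changed by 0.13 ± 0.39 (SD, n = 8) while IL7R changed by 1.36. More dendritic cells may contribute and could not be excluded: 9 identity members had a median of 0.24 ± 0.35 against 0.86 ± 0.41 for 17 maturation members, and of the identity members ZBTB46 (0.53) and FLT3 (1.43, at 0.242 CPM in DMSO) were called, while IRF4 (0.87), CLEC10A (0.24), CD1A (0.22), CD1C (0.10), CD1E (0.06), CD1B (-0.44) and XCR1 (-0.46) were not. A response of the macrophages to LCL161 stays open as well: the list's median was above 0 in 16 of 16 pairs of libraries from the 8 donors, which more dendritic cells would also give.

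Mitochondrially encoded genes such as MT-CO3 and ribosomal protein genes such as RPS6 were higher with LCL161 plus IFN-γ than with IFN-γ. A gain of short transcripts could not be excluded: 264 other genes whose principal transcripts have at most 1000 bases had a median of 0.11 ± 0.124 (SD, n = 8; above 0 in 7 of 8 donors, 77 called higher and 19 lower), against 0.28 ± 0.24 for ribosomal and 0.57 ± 0.33 for mitochondrially encoded genes. The first test of length used 2357 genes with summed exonic lengths of 1648 to 5936 bases, and their median (-0.028 ± 0.077) stayed below its preset bound. Summed exonic length is not transcript length: the ribosomal genes had a median principal transcript length of 1012.75 bases. How many of the 2357 genes have short transcripts was not examined, so this test decides nothing about short transcripts. Scaling was not tested by the other factors either, which kept at least 99.8% of either median but moved the median over all genes by at most 0.012. A larger LCL161 effect with IFN-γ is a candidate explanation for the mitochondrial share (exact paired permutation p = 0.0391, and 0.122 after adjustment). RNA quality stays open: in the same comparison the share of protein-coding genes was lower and more genes were detected, each in 8 of 8 donors. But more genes were detected in 8 of 8 donors with LCL161 against DMSO too, where 0 of 13 mitochondrially encoded genes were called. There the mitochondrial share was 2.69% in DMSO and 3.06% in LCL161, higher in 6 of 8 donors (exact paired permutation p = 0.0703, and 0.0988 after adjustment).

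Labels were swapped within donors in 40 of the 128 possible splits of the libraries of each comparison, in fits of only the groups compared without the robust option, so that the counts differ slightly from those of the robust fits. In the order LCL161, IFN-γ and the combination against DMSO, the combination against IFN-γ and against LCL161, and LCL161 against IFN-γ, the real labels called 3686, 7207, 7226, 3978, 6514 and 7335 genes, and the highest of the other splits 0, 3946, 0, 2, 3 and 0. In each of these 1 of 40 splits, the real one, was as large. That is the smallest share that 40 splits can give, so chance is not excluded by them. For the interaction the real labels called 0 genes, so that 40 of 40 splits were as large whatever the data, the highest of the others being 0, and the splits decide nothing.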
